A study of Mus musculus with 27 samples.

How the data were processed

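RNA of TX1072 mouse embryonic stem cells was measured in 27 libraries, grouped by the labels into 6 groups by line (BglG-GFP or BglG-GFP-SPOC) and treatment (untreated, Dox, Dox+Auxin). Per the labels' protocols, cells grew in medium with serum, 2i and LIF, RNA was taken with an RNeasy kit, samples with a RIN score above 9 went into TruSeq libraries, and these were sequenced as paired ends on a HiSeq2500. The submitters' processing notes name Trim Galore 0.4.4, STAR 2.5.3a, Picard 2.18.2, featureCounts, DESeq2 1.18.1 and the build mm10, with no role or order. The gene annotation, the strand setting and the way reads were assigned to alleles are not given in the sources used here.

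The table deposited by the authors holds raw counts per gene of both alleles together, RPKM values, and counts assigned to each allele, for 53801 genes; per the file headers these are separate columns for each library. The deposited RPKM were checked to be the counts of the same name divided by 1 length per gene and 1 factor per library, and were not used further. Gene names and positions came from GENCODE M21 (GRCm38), which held 53706 of the IDs. Total counts ranged from 28936459 to 45489094 per library and the 10 most counted genes held 2.57% to 2.94% of them. Mitochondrially encoded genes had no counts (0.0% in every library), so that list, fixed beforehand, had 0 genes tested. Intervals on shares cover counting error only. The design text calls the replicates biological. All pairs of libraries within groups differed by more than sampling noise, and none was counted as a duplicate. The lowest chi-square per gene was 1.93, between SPOC Dox+Auxin replicates 1 and 2. Other pairs of that group had 8.17 to 16.3. Whether these libraries came from separate cultures was not tested.

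Counts were normalised by TMM, filtered with filterByExpr to 18363 genes and fitted in 1 model with a term per group over all 27 libraries with edgeR 4.0.16 (R 4.3.3; robust quasi-likelihood fit and test). The 9 comparisons were Dox, and Dox+Auxin, against untreated and Dox+Auxin against Dox within each line, SPOC against GFP untreated and with Dox+Auxin, and the line by treatment interaction of Dox+Auxin against untreated. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called, and the standard error was taken from the fold change and the F statistic. Fold changes are log2. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, adjusted over 243 tests of 27 lists; of 74 calls with the preset correlation and 16 with the estimated one, the text names those it discusses. The 28 lists comprised naive pluripotency, formative and primed, primitive endoderm, mesoderm and definitive endoderm, neural, trophoblast, fibroblast feeder, two-cell-like, Notch and RBPJ targets, aryl hydrocarbon receptor targets, mitochondrially encoded, ATF4 targets, mitochondrial protein quality control, p53 targets, MAPK feedback, X-linked escape, X-inactivation centre, X-linked ES cell regulators, X-linked housekeeping, Xist silencing factors, the NCoR SMRT HDAC3 complex, imprinted, germline, cholesterol synthesis, cell cycle, heat shock and interferon genes, and all X-linked genes. Lists, comparisons, tests and the naming rule were fixed before the data were examined. The rule named Xist, Tsix and Spen, list members, and per comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the libraries compared, leaving out predicted genes, Rik names, pseudogenes and unnamed IDs. Values of some genes that the rule names are not reported here.

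X-linked output (X-linked minus autosomal median of log2 CPM, each gene centred on its mean, for genes with a mean of at least 1 CPM) was added after the data had been seen and tested by exact two-sided permutation of libraries; for the interaction, differences between libraries of the same replicate number within a line were permuted between lines. As the numbers did not meet the rule set for pairing, that test was repeated over all ways to match libraries within each line. This step was added later. Because the names of the allelic columns disagreed with the totals, the planned tests on allelic counts were not run.

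The steps were tested on simulated counts with 200 changed genes drawn from the means and library sizes here. For GFP Dox against untreated (18161 genes) edgeR recovered 48% of genes at the smallest fold simulated, 68% of genes changed 1.5-fold, 86% at 2-fold and 100% at 4-fold, with 4 of 155 calls false. For SPOC Dox against untreated (18158 genes) it recovered 58%, 66%, 84% and 98%, with 3 of 156 false. The simulated genes varied independently, with as many rises as falls. Broad shifts in 1 direction, related replicates and outlying libraries were not simulated, so these rates may not hold for the data here. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a mean of at least 5 CPM, only the groups compared, autosomal genes only, a replicate block and leaving out each library. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.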

Results

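Read counts per gene were analysed from 27 RNA sequencing libraries of TX1072, a mouse embryonic stem cell line from a cross of BL/6J and CAST-EiJ mice. In this line doxycycline switches on Xist, the non-coding RNA that coats and silences the X chromosome it is made from, on the BL/6J chromosome. The cells carry SPEN, a repressor protein that binds Xist RNA, fused to an auxin-inducible degron, so that auxin depletes it. The GFP line expressed BglG-GFP, in which BglG is a bacterial RNA-binding protein used to bring its fusion partner to Xist RNA. The SPOC line expressed BglG-GFP-SPOC, which adds the SPOC domain, the C-terminal domain of SPEN. Cells of each line were untreated, given doxycycline at 1 ug/mL for 24 h (Dox), or given auxin for 12 h and then doxycycline with auxin for 24 h (Dox+Auxin). Each group held 4 libraries in the GFP line and 5 in the SPOC line, while the submitters' design text speaks of 4 biological replicates. Total counts ranged from 28936459 to 45489094 per library, and 18363 genes passed the filter on low counts. No group received auxin alone, so Dox+Auxin differed from untreated by doxycycline, auxin and SPEN depletion together. No group received doxycycline without inducible Xist either, so Dox differed from untreated by doxycycline and Xist induction together. By the labels each construct was in 1 line, so an effect of SPOC cannot be told apart from other differences between the lines.

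Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254 in GRCm38) was low in untreated cells and high with doxycycline. In the GFP line its level was 6.47 ± 1.03 CPM (library-size-scaled counts; SD, n = 4) untreated, 840 ± 88.1 with Dox and 500 ± 109 with Dox+Auxin. In the SPOC line it was 385 ± 62.3 CPM (SD, n = 5) with Dox and 338 ± 48.2 with Dox+Auxin. Of the SPOC untreated libraries, 4 lay between 1.03 and 1.69 CPM, and the library labelled untreated replicate 2 held 178 CPM. The standard error of Xist was 0.70 or more in each of the 9 comparisons with this library in the shared fit and 0.37 or less without it. Tsix, the antisense partner that overlaps Xist, was at 7.19 ± 0.531 CPM untreated and 8.94 ± 2.02 with Dox in the GFP line (SD, n = 4), so its counts did not follow the rise of Xist. The strand setting of the counting is not given in the sources used here, and how reads from the shared stretch were counted is uncertain. Spen (ENSMUSG00000040761, chromosome 4, 141467890 to 141538597) was 174 ± 12.1, 197 ± 15.4 and 860 ± 223 CPM in the untreated, Dox and Dox+Auxin groups of the GFP line. In the SPOC line, whose construct contains part of the Spen sequence, it was 343 ± 11.4, 353 ± 15.0 and 1052 ± 114 CPM. These are RNA counts, and SPEN protein was not measured.

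**Figure D1:**
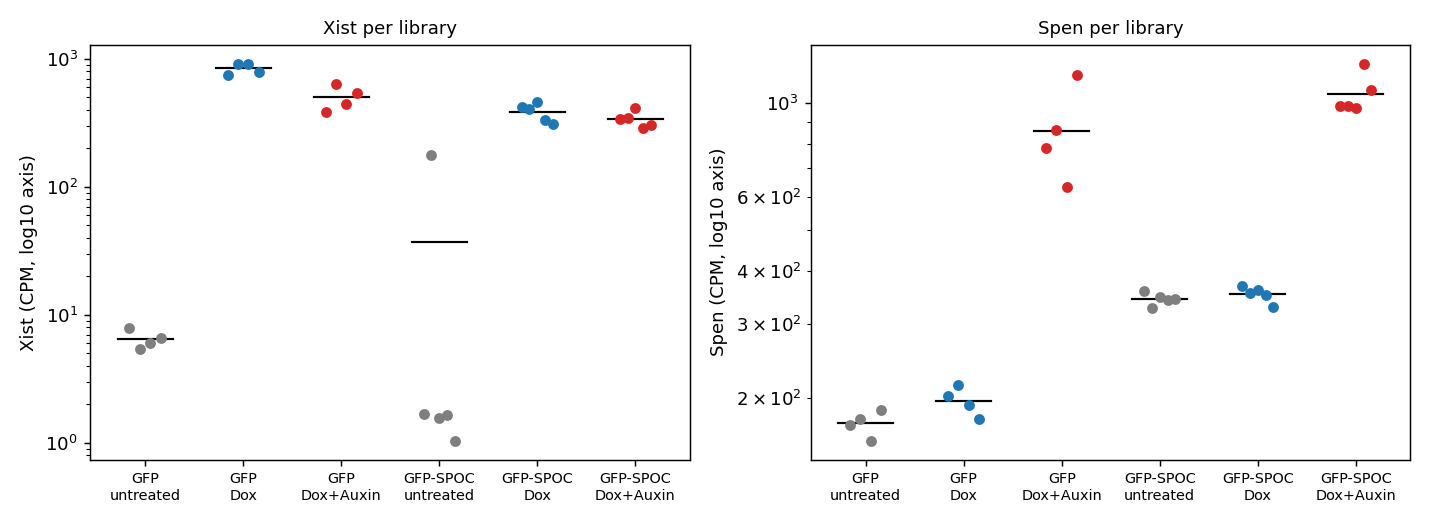
Xist (left) and Spen (right) in CPM on log10 axes, with 1 point per library and a bar at the mean of each of the 6 groups. Xist is between 289.5 and 918 CPM in the doxycycline groups, and Spen is between 634 and 1242 CPM in the Dox+Auxin groups.

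Dox against untreated in the GFP line asked what doxycycline, which induces Xist, does with SPEN present. X-linked genes fell broadly. Of 731 X-linked genes tested without Xist and Tsix, 536 fell and 2 rose, with a median log2 fold change of -0.64 against 0.01 for 17608 autosomal genes. The list of X-linked housekeeping genes fell almost as a whole, with 24 of 25 members lower and all 25 lower adjusted over the list alone. Among them Hprt, the purine salvage enzyme, fell by 0.65 (SE 0.05, adjusted p = 2.1e-11), Magt1 by 0.80 (SE 0.07, adjusted p = 1.1e-09) and Rbmx, a splicing factor, by 1.02 (SE 0.10, adjusted p = 1.6e-08). Of 14 X-linked ES cell regulators, 12 fell (12 adjusted over the list alone), including Rlim, the ubiquitin ligase that activates Xist, which fell from 213 ± 11.3 to 93.9 ± 2.67 CPM (SD, n = 4; edgeR adjusted p = 2.6e-07), and Sox3, by 1.32 (SE 0.10, adjusted p = 2.5e-11). Genes known to escape X inactivation were also lower, 11 of 14 (12 adjusted over the list alone). Kdm5c, a histone demethylase, fell by 0.40 (SE 0.05, adjusted p = 8.9e-07), and Kdm6a, another, was the 1 member that rose, by 0.16 (SE 0.04, adjusted p = 0.0011). Of the X-inactivation centre list, 6 of 10 members fell and Xist rose (the same counts adjusted over the list alone).

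The largest falls by the naming rule were all X-linked, led by Magee2 (log2 fold change -2.82, SE 0.31, adjusted p = 8.5e-08), with Firre at -1.89 (SE 0.17, adjusted p = 1.6e-08) and Cited1 at -1.70 (SE 0.25, adjusted p = 2.7e-05). Besides Xist (7.03, SE 1.08, adjusted p = 5.0e-05), the largest rises were autosomal: Duox1, an NADPH oxidase, at 4.13 (SE 0.26, adjusted p = 6.0e-13), Atp2a3, a calcium pump, at 1.62 (SE 0.14, adjusted p = 4.5e-10), and the transcription factor Tfap2a at 1.34 (SE 0.15, adjusted p = 6.9e-08). Cholesterol synthesis genes were lower, 14 of 20 with 1 higher (the same counts adjusted over the list alone). Insig1, a sterol sensor, fell by 0.38 (SE 0.07, adjusted p = 3.0e-04) and the X-linked Nsdhl by 0.68 (SE 0.06, adjusted p = 4.7e-09). Spen (0.18, SE 0.12, adjusted p = 0.33) and Tsix (0.31, SE 0.20, adjusted p = 0.31) did not pass. In all, 1851 genes rose and 1986 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By camera the housekeeping, ES cell regulator and escape lists and all X-linked genes moved down against other genes (adjusted p = 4.2e-31, 1.4e-15, 2.5e-08 and 7.5e-85). With an estimated correlation their adjusted p was 0.023, 0.019, 0.044 and 0.0016. The cholesterol call (adjusted p = 2.7e-06) was lost, with adjusted p = 0.44 with an estimated correlation, as was that of the X-inactivation centre (adjusted p = 0.0078, and adjusted p = 0.21 with an estimated correlation).

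Dox+Auxin against untreated in the GFP line asked what was left of this when auxin depleted SPEN. The X-linked fall was mostly absent. Of the 731 X-linked genes, 191 fell and 107 rose, with a median of -0.07, and the housekeeping list had 3 of 25 members lower and 3 higher (the same counts adjusted over the list alone). Hprt was at -0.07 (SE 0.05, adjusted p = 0.31), Msn fell by 0.46 (SE 0.05, adjusted p = 2.6e-08), Lamp2 rose by 0.53 (SE 0.04, adjusted p = 1.3e-11) and Rlim rose by 0.94 (SE 0.12, adjusted p = 2.5e-06). Xist itself rose by 6.28 (SE 1.06, adjusted p = 6.5e-05) and Spen mRNA by 2.31 (SE 0.12, adjusted p = 3.8e-12). Ftx, a non-coding gene next to Xist, rose by 1.66 (SE 0.19, adjusted p = 3.4e-08). Tsix was at -0.38 (SE 0.21, adjusted p = 0.16).

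Several autosomal programmes moved in the same comparison. Targets of the aryl hydrocarbon receptor rose, 7 of 9 (7 adjusted over the list alone), led by the cytochrome P450 genes Cyp1a1 (log2 fold change 5.14, SE 0.31, adjusted p = 2.2e-11) and Cyp1b1 (3.40, SE 0.42, adjusted p = 1.1e-06) and by the receptor's repressor Ahrr (2.32, SE 0.19, adjusted p = 3.7e-11). Two-cell-like genes, which mark a rare state of stem cell cultures, fell in 17 of 19 cases (17 adjusted over the list alone). Zscan4a was at -1.98 (SE 0.16, adjusted p = 1.3e-10) and Zfp352 at -1.93 (SE 0.18, adjusted p = 4.4e-10). The Zscan4, Usp17l and Tdpoz members have near-identical copies and their counts are uncertain. Of 20 p53 targets, 14 rose and 2 fell (15 and 2 adjusted over the list alone), with Phlda3 at 0.64 (SE 0.06, adjusted p = 2.4e-09). Of 24 ATF4 targets, 15 fell and 2 rose (15 and 3 adjusted over the list alone), with Chac1, a glutathione-degrading enzyme, at -1.03 (SE 0.11, adjusted p = 1.5e-08). The largest falls included Sh3rf2 (-2.51, SE 0.19, adjusted p = 8.1e-12) and Ccnd2, cyclin D2 (-2.38, SE 0.20, adjusted p = 1.7e-10). In all, 3646 genes rose and 3373 fell by edgeR. The aryl hydrocarbon receptor call (camera adjusted p = 2.2e-05) held (adjusted p = 0.025 with an estimated correlation). The calls of two-cell-like genes (adjusted p = 1.8e-12), p53 targets (9.5e-05) and ATF4 targets (1.1e-04) were lost: adjusted p = 0.0705, 0.46 and 0.46 with an estimated correlation.

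Dox+Auxin against Dox in the GFP line compared cells with and without auxin, both with doxycycline. X-linked genes were higher with auxin: 465 rose and 34 fell, with a median of 0.52, and 24 of 25 housekeeping and 11 of 14 ES cell regulator genes rose (24 and 11 adjusted over the list alone), with 1 ES cell regulator lower. Ftx rose by 3.25 (SE 0.23, adjusted p = 1.0e-12), Magt1 by 1.12 (SE 0.07, adjusted p = 5.7e-13), Rlim by 2.12 (SE 0.13, adjusted p = 9.2e-12) and Hprt by 0.59 (SE 0.05, adjusted p = 4.6e-11). Kdm6a fell by 0.31 (SE 0.04, adjusted p = 2.7e-08), as did Nr0b1, an X-linked pluripotency regulator, by 0.39 (SE 0.07, adjusted p = 1.8e-05). Xist was at -0.75 (SE 0.78, adjusted p = 0.46) and, without the SPOC library labelled untreated replicate 2 in the shared fit, fell by 0.75 (SE 0.14, adjusted p = 2.1e-04). Its libraries held 382 to 630 CPM with Dox+Auxin and 747 to 918 with Dox (exact two-sided permutation p = 0.0286, the smallest possible). Tsix fell by 0.68 (SE 0.21, adjusted p = 0.0078). Among autosomal genes, Inhbb, an activin subunit, fell by 2.60 (SE 0.11, adjusted p = 3.0e-17) and Dusp6, a MAP kinase phosphatase, by 2.24 (SE 0.14, adjusted p = 5.1e-14). In all, 4528 genes rose and 4204 fell by edgeR. The camera calls of housekeeping genes (adjusted p = 2.9e-14), ES cell regulators (9.0e-07) and all X-linked genes (8.9e-24) were lost, with adjusted p = 0.15, 0.14 and 0.0705 with an estimated correlation. That correlation was estimated with the SPOC library labelled untreated replicate 2 among the libraries.

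Dox against untreated in the SPOC line again showed a broad fall of X-linked genes. Of the 731, 458 fell, with a median of -0.39. Housekeeping genes fell in 23 of 25 cases (25 adjusted over the list alone), ES cell regulators in 12 of 14 (12 adjusted over the list alone, with 1 higher) and escape genes in 10 of 14 (11 adjusted over the list alone, with 1 higher). Hprt fell by 0.47 (SE 0.04, adjusted p = 7.9e-09), Nsdhl by 0.44 (SE 0.06, adjusted p = 3.6e-06), Magt1 by 0.66 (SE 0.06, adjusted p = 1.8e-08) and Magee2 by 2.73 (SE 0.30, adjusted p = 2.6e-07). Rlim fell from 216 ± 39.3 to 108 ± 12.8 CPM (SD, n = 5; edgeR adjusted p = 1.3e-06). Xist rose by 3.37 (SE 0.79, adjusted p = 0.0058), and without the library labelled untreated replicate 2 by 8.01 (SE 0.24, adjusted p = 1.0e-15). Duox1 rose by 2.10 (SE 0.25, adjusted p = 3.3e-07), and cholesterol synthesis genes fell in 12 of 20 cases (15 adjusted over the list alone, with 1 higher). Spen was at 0.04 (SE 0.11, adjusted p = 0.87) and Tsix at 0.18 (SE 0.18, adjusted p = 0.61). In all, 1132 genes rose and 1346 fell by edgeR, and 1272 and 1420 without that library. The housekeeping, ES cell regulator, escape and all-X calls (camera adjusted p = 4.1e-29, 1.5e-16, 5.5e-09 and 1.7e-69) held, with adjusted p = 0.026, 0.017, 0.036 and 0.0031 with an estimated correlation. The cholesterol call (adjusted p = 1.3e-06) was lost, with adjusted p = 0.41 with an estimated correlation. The count with a replicate block is given with the processing alternatives.

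Dox+Auxin against untreated in the SPOC line asked whether SPOC on Xist RNA silences when SPEN is depleted. More X-linked genes fell than rose, 311 against 40 of 731, with a median of -0.21, and without the library labelled untreated replicate 2 these were 357 and 32 of 729, with a median of -0.24. Hprt fell by 0.33 (SE 0.04, adjusted p = 7.9e-07), Pgk1, a glycolytic enzyme, by 0.82 (SE 0.13, adjusted p = 3.4e-05) and Magee2 by 2.51 (SE 0.29, adjusted p = 1.8e-07). Of the housekeeping list 10 of 25 fell and 1 rose (11 and 1 adjusted over the list alone), of the ES cell regulators 7 of 14 fell (7 adjusted over the list alone), and of the X-inactivation centre 7 of 10 fell and Xist rose (8 and 1 adjusted over the list alone). Without the library labelled untreated replicate 2, 13 of 25 housekeeping genes fell and 1 rose, and 10 of 14 ES cell regulators fell. The X-inactivation centre then had 7 of 10 members lower and 1 higher. In that centre Ftx fell by 1.12 (SE 0.22, adjusted p = 1.8e-04) and Rlim was at -0.10 (SE 0.11, adjusted p = 0.51). Xist rose by 3.18 (SE 0.79, adjusted p = 0.0033), and by 7.83 (SE 0.24, adjusted p = 3.2e-15) without that library; Spen mRNA rose by 1.62 (SE 0.11, adjusted p = 2.0e-10) and Tsix was at -0.40 (SE 0.19, adjusted p = 0.10), and at -0.54 (adjusted p = 0.014) without SPOC untreated replicate 5.

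Autosomal programmes in this comparison included the aryl hydrocarbon receptor targets, of which 7 of 9 rose (7 adjusted over the list alone), with Cyp1a1 at 4.51 (SE 0.28, adjusted p = 5.3e-11) and Ahrr at 2.67 (SE 0.18, adjusted p = 1.9e-12). Two-cell-like genes fell in 17 of 19 cases (17 adjusted over the list alone), with Zscan4a at -2.29 (SE 0.16, adjusted p = 1.2e-11) and Tcstv1 at -2.20 (SE 0.23, adjusted p = 1.0e-08), while Zfp600 rose by 0.32 (SE 0.08, adjusted p = 0.0024). ATF4 targets fell in 14 of 24 cases and rose in 2 (14 and 2 adjusted over the list alone), with Chac1 at -0.86 (SE 0.10, adjusted p = 1.2e-07). Stc1, a secreted glycoprotein, fell by 2.75 (SE 0.48, adjusted p = 1.1e-04). In all, 3061 genes rose and 3056 fell by edgeR, and 2943 and 2852 without the library labelled untreated replicate 2. The aryl hydrocarbon receptor and two-cell-like calls (camera adjusted p = 6.2e-07 and 4.4e-15) held, with adjusted p = 0.017 and 0.044 with an estimated correlation. The calls of all X-linked genes (5.4e-11), the X-inactivation centre (0.0021), ES cell regulators (0.0029), housekeeping genes (0.027) and ATF4 targets (1.9e-04) were lost: adjusted p = 0.35, 0.13, 0.46, 0.73 and 0.46 with an estimated correlation.

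Dox+Auxin against Dox in the SPOC line showed 277 X-linked genes higher and 63 lower, with a median of 0.16. Housekeeping genes rose in 17 of 25 cases (18 adjusted over the list alone, with 1 lower), with Magt1 at 0.72 (SE 0.06, adjusted p = 1.0e-09) and Hprt at 0.14 (SE 0.04, adjusted p = 0.014), while Pgk1 was at -0.13 (SE 0.13, adjusted p = 0.48). Rlim rose by 0.90 (SE 0.11, adjusted p = 2.1e-06) and Firre, a non-coding gene that escapes X inactivation, by 1.59 (SE 0.14, adjusted p = 1.9e-08). Xist was at -0.19 (SE 0.70, adjusted p = 0.88; SE 0.13 and adjusted p = 0.30 without the library labelled untreated replicate 2 in the fit), Tsix fell by 0.58 (SE 0.18, adjusted p = 0.018, and 0.0559, 0.0581 and 0.0509 without Dox replicate 1, Dox replicate 3 or Dox+Auxin replicate 4) and Spen rose by 1.58 (SE 0.11, adjusted p = 3.0e-10). Cyp1a1 rose by 4.65 (SE 0.28, adjusted p = 4.8e-11), Mobp by 1.82 (SE 0.09, adjusted p = 4.9e-14) and the neural factor Sox21 by 1.47 (SE 0.11, adjusted p = 1.1e-10), and Sp110, of the two-cell-like list, fell by 1.76 (SE 0.18, adjusted p = 5.6e-09). Of the aryl hydrocarbon receptor targets 7 of 9 rose, and of the two-cell-like genes 16 of 19 fell and 1 rose (the same counts adjusted over the list alone). In all, 3043 genes rose and 2833 fell by edgeR. The calls of these 2 lists (camera adjusted p = 5.2e-06 and 5.7e-14) held, with adjusted p = 0.020 and 0.0496 with an estimated correlation. The camera calls of housekeeping genes (adjusted p = 1.0e-08) and all X-linked genes (1.1e-07) were lost, with adjusted p = 0.35 and 0.46 with an estimated correlation.

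**Figure D2:**
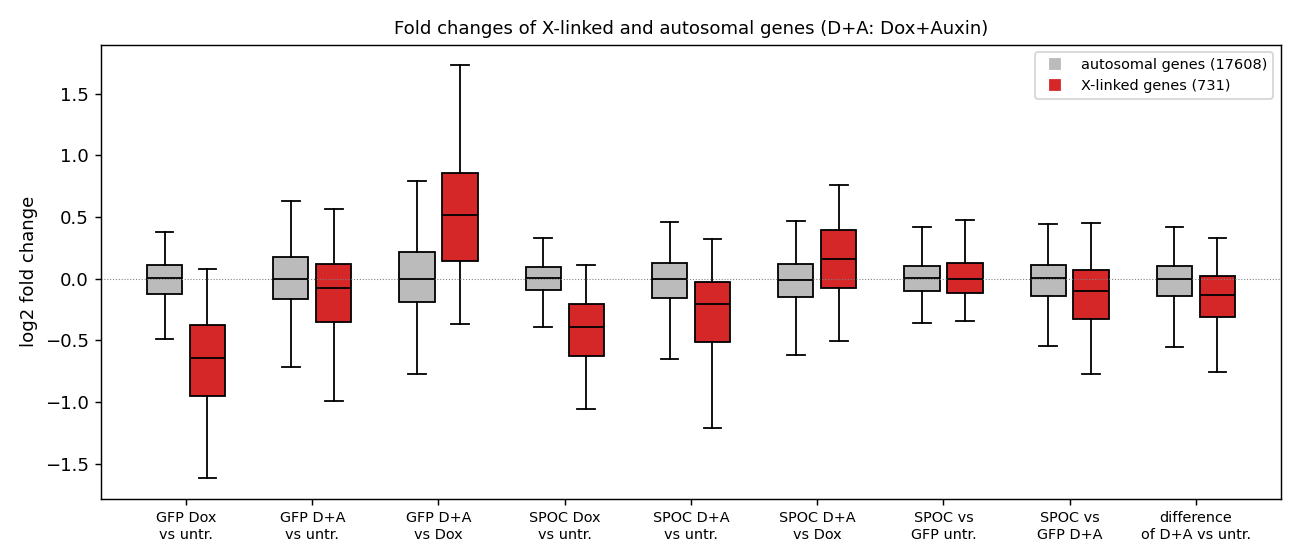
Log2 fold changes of 17608 autosomal (grey) and 731 X-linked genes (red) in the 9 comparisons; boxes span the quartiles with a line at the median and whiskers reach the 5th and 95th percentiles. The X-linked median is -0.64 for Dox against untreated in the GFP line and -0.39 in the SPOC line.

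The SPOC and GFP lines were also compared untreated, as a baseline without induced Xist. X-linked genes differed little as a set: 36 were higher and 32 lower in the SPOC line of 731, with a median of -0.00. Without the library labelled untreated replicate 2 the X-linked counts were 56 and 14 of 729. Spen was higher by 0.98 (SE 0.11, adjusted p = 4.1e-05). The homeobox gene Nkx6-3, among the largest falls, was at -0.97 (SE 0.17, adjusted p = 6.5e-04). Of 24 ATF4 targets, 10 were lower (11 adjusted over the list alone), with Atf5 at -0.38 (SE 0.04, adjusted p = 6.9e-06). Of 12 mesoderm and definitive endoderm genes, 4 were higher (6 adjusted over the list alone), among them the transcription factor Foxh1 at 0.27 (SE 0.06, adjusted p = 0.0069). Xist was at 2.54 (SE 1.01, adjusted p = 0.11), and without the library labelled untreated replicate 2 at -2.11 (SE 0.33, adjusted p = 7.3e-04); Tsix was at 0.12 (SE 0.19, adjusted p = 0.73). In all, 1063 genes were higher and 1059 lower by edgeR, and 847 and 866 without that library. The total of 2122 was 1406 without SPOC untreated replicate 5, and 1076 and 1035 without GFP untreated replicates 1 and 2. The mesoderm call (camera adjusted p = 1.5e-04) held, with adjusted p = 0.022 with an estimated correlation, and the ATF4 call (1.6e-07) was lost, with adjusted p = 0.28 with an estimated correlation.

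With Dox+Auxin, X-linked genes were lower in the SPOC line than in the GFP line, 214 against 33 higher, with a median of -0.10. The X-inactivation centre had 5 of 10 members lower (7 adjusted over the list alone): Ftx at -2.74 (SE 0.20, adjusted p = 3.3e-10) and Rlim at -1.02 (SE 0.12, adjusted p = 1.9e-06) were among them. ES cell regulators were lower in 11 of 14 cases and higher in 1 (the same counts adjusted over the list alone), and housekeeping genes lower in 12 of 25 (13 adjusted over the list alone), with Hprt at -0.31 (SE 0.05, adjusted p = 1.5e-05) and Pdha1, a subunit of pyruvate dehydrogenase, at -0.37 (SE 0.04, adjusted p = 1.8e-07). On autosomes, p53 targets were lower in 11 of 20 cases (12 adjusted over the list alone, with 1 higher), with Btg2 at -0.59 (SE 0.06, adjusted p = 1.4e-08). Cholesterol synthesis genes were lower in 11 of 20 cases (11 adjusted over the list alone), and naive pluripotency genes higher in 10 of 18 (10 adjusted over the list alone), with Tet2 at 0.37 (SE 0.09, adjusted p = 0.0044). Dio3, a thyroid hormone deiodinase, was higher by 1.57 (SE 0.23, adjusted p = 2.7e-05). Xist (-0.56, SE 0.74, adjusted p = 0.63), Tsix (0.10, SE 0.20, adjusted p = 0.76) and Spen (0.29, SE 0.11, adjusted p = 0.062) did not pass. Without GFP Dox+Auxin replicate 4, Spen passed at 0.47 (adjusted p = 3.4e-04), and with all libraries it passed in the DESeq2 Wald test at 0.29 (adjusted p = 0.047). Without the library labelled untreated replicate 2 in the fit, Xist was lower in the SPOC line at -0.56 (SE 0.14, adjusted p = 0.0044), and by exact permutation of its level p was 0.0238. In all, 2048 genes were higher and 2475 lower by edgeR. The X-inactivation centre call (camera adjusted p = 3.0e-05) held, with adjusted p = 0.034 with an estimated correlation. Those of ES cell regulators (2.0e-05), housekeeping genes (4.2e-05), p53 targets (8.9e-06), cholesterol synthesis (1.6e-04), naive pluripotency (8.3e-04) and all X-linked genes (1.5e-05) were lost: adjusted p = 0.23, 0.54, 0.41, 0.54, 0.35 and 0.54 with an estimated correlation.

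The interaction tested whether the lines differed in their change from untreated to Dox+Auxin. With 1 line per construct, it cannot tell SPOC from other differences between the lines. Of the X-linked genes 58 changed more downward in the SPOC line and 1 more upward, with a median difference of -0.13, and without the library labelled untreated replicate 2 these were 143 and 1 of 729. In the X-inactivation centre, Ftx was at -2.78 (SE 0.29, adjusted p = 1.9e-06) and Rlim at -1.04 (SE 0.16, adjusted p = 0.0023). Sox3 was at -0.68 (SE 0.12, adjusted p = 0.0040) and Pdha1 at -0.27 (SE 0.06, adjusted p = 0.0090). On autosomes the chemokine gene Cxcl12 was at -2.39 (SE 0.37, adjusted p = 9.0e-04), Cobl at 0.98 (SE 0.10, adjusted p = 3.9e-06) and the stem cell factor Foxd3 at 0.94 (SE 0.12, adjusted p = 7.2e-05). Spen was at -0.69 (SE 0.16, adjusted p = 0.024, and 0.0547 without GFP untreated replicate 3), and Xist (-3.10, adjusted p = 0.19) and Tsix (-0.02, SE 0.28, adjusted p = 0.98) did not pass. Without the library labelled untreated replicate 2, Xist was at 1.55 (SE 0.37, adjusted p = 0.022). By list, 4 of 10 genes of the X-inactivation centre (6 adjusted over the list alone), 3 of 14 ES cell regulators (6, with 1 upward) and 3 of 25 housekeeping genes (6) passed downward, and without that library 5, 7 and 10 did. In all, 220 genes passed upward and 221 downward by edgeR, and 297 and 354 without that library. The camera calls of the X-inactivation centre (adjusted p = 1.6e-04), ES cell regulators (1.6e-04), housekeeping genes (3.6e-04) and all X-linked genes (5.0e-07) had adjusted p = 0.0496, 0.34, 0.58 and 0.46 with an estimated correlation, so that only the first held. The total of 441 was 207 to 278 without any 1 of SPOC untreated replicate 4, GFP untreated replicates 3 and 4 and GFP Dox+Auxin replicates 1, 2 and 3, and 865 without GFP Dox+Auxin replicate 4. The count with a replicate block, several times higher, is given with the processing alternatives.

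To give 1 value per library, X-linked output was taken as the median log2 level of 554 X-linked genes minus that of 13640 autosomal genes, a measure chosen after the data had been seen. Relative to the untreated mean of the same line, it was -0.62 ± 0.02 (SD, n = 4) with Dox and -0.06 ± 0.01 with Dox+Auxin in the GFP line, and -0.39 ± 0.01 (SD, n = 5) and -0.20 ± 0.01 in the SPOC line. These SDs leave out the spread of the untreated libraries, with an SD of 0.01 in the GFP line and 0.12 in the SPOC line. Each difference within the GFP line had p = 0.0286 in an exact two-sided permutation test, the smallest that 4 against 4 allows (adjusted p = 0.0429 over the 9 comparisons). In the SPOC line Dox against untreated and Dox+Auxin against Dox (0.19) had p = 0.00794 in the exact test (adjusted p = 0.0238). Dox+Auxin against untreated had p = 0.0397 (exact, adjusted p = 0.0510) and, without the library labelled untreated replicate 2, a difference of -0.25 with p = 0.00794 (exact). With Dox+Auxin the SPOC line was lower than the GFP line by -0.15 (exact p = 0.00794, adjusted p = 0.0238). The difference between lines in the change from untreated to Dox+Auxin was -0.14 (exact p = 0.0635 with libraries matched by replicate number, and 0.0476 to 0.0714 over 2880 ways to match them). Without replicate 2 of SPOC untreated and Dox+Auxin it was -0.19 (exact p = 0.0286, the smallest possible, in all 576 ways). With Dox+Auxin, 10.1% of the Dox fall was present in the GFP line (8.98% to 10.6% with each library left out) and 51.0% in the SPOC line (48.9% to 56.7%). The 56.7% was the share without the library labelled untreated replicate 2, where Dox differed from untreated by -0.45. These shares were not adjusted for the level of Xist. Its mean with Dox and Dox+Auxin was 840 and 500 CPM in the GFP line and 385 and 338 in the SPOC line. Untreated, the SPOC line differed from the GFP line by -0.01 (exact p = 1) and, without the library labelled untreated replicate 2, by 0.0384 (exact p = 0.0286, the smallest possible).

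**Figure D3:**
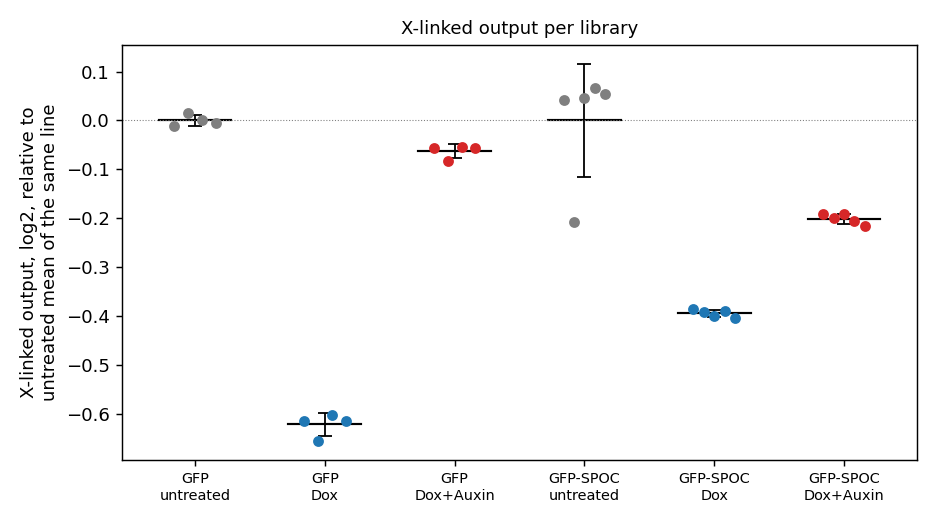
X-linked output per library (log2, relative to the untreated mean of the same line), with 1 point per library and bars for the mean and SD of each group. The GFP Dox libraries lie between -0.66 and -0.60, and 1 SPOC untreated library lies at -0.21.

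The deposited table also holds counts assigned to the BL/6J and CAST-EiJ alleles, but their column names could not be used to place them in groups. The sum of both alleles exceeded the total count of the same name in 1303 to 5292 genes in each of the 27 pairs of columns, which a part of a total cannot do. The planned comparisons of allelic ratios were therefore not made, and values over the 27 pairs are given without group. The median BL/6J share was 20.2% to 50.6% over 457 X-linked genes (median over pairs 39.2%) and 50.2% to 50.5% over 12287 autosomal genes. Allelic Xist was 1.30 to 1038 CPM of the allelic counts, with a median BL/6J share of 99.1%. The pair with the highest Xist (13086 counts, 99.5% BL/6J) had an X-linked median of 22.4%, and the pair with the lowest Xist (14 counts) one of 49.5%. In the pair with the lowest X-linked median, 51 of 262 X-linked genes with a mean of at least 200 allelic counts were under 10% BL/6J and 20 were over 40%. Rlim had 9.39% (exact binomial 95% interval 7.77% to 11.2%) there and Kdm6a 55.0% (52.4% to 57.5%).

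**Figure D4:**
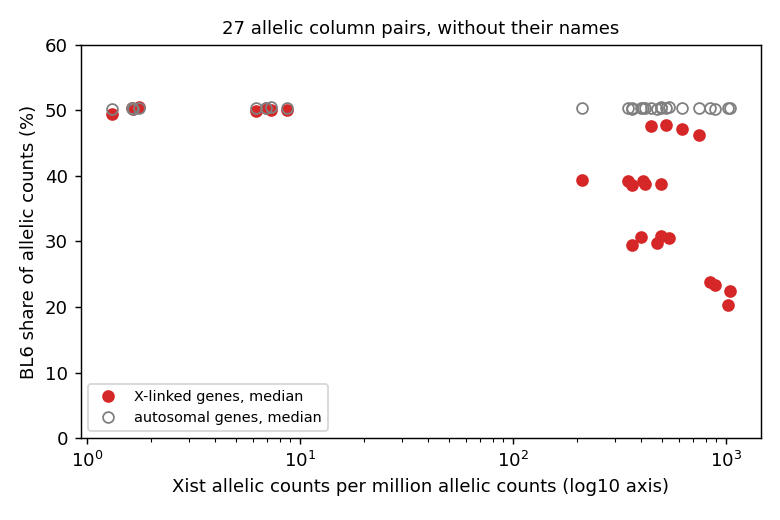
Median BL/6J share of allelic counts (%) over X-linked (filled) and autosomal genes (open) against Xist in CPM of the allelic counts (log10 axis), for 27 pairs of allelic columns shown without their names. The autosomal medians lie at 50.2% to 50.5% and the X-linked medians at 20.2% to 50.6%.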

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

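The tests of labels, of added Spen counts (also with libraries left out) and of the order of allelic columns, the counts of other splits and all results on X-linked output were chosen after the results were seen; the slope test of the SPOC library below was written before its result was seen. Within groups, 42 comparisons of the most distant library with the others were made and 3 stood apart. Chance gives about 1 in 20 such groups.

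The library labelled SPOC untreated replicate 2 lay far from the other 4 untreated libraries, with 178 CPM of Xist against 1.03 to 1.69 and X-linked output of -0.21 against 0.04 to 0.07. A Dox library under a wrong label is argued against by its X-linked output, at 58.1% of the Dox fall, where the Dox libraries lay at 98.3% to 102%, and a Dox+Auxin library by its Spen level, 326 CPM against 973 to 1242. Over 3073 autosomal genes that passed for Dox in the GFP line, its deviation followed the Dox change of the SPOC line with a slope of 0.414, against -0.0428 to 0.0336 in the other untreated libraries, so a candidate explanation is that part of the cells or of the RNA had been exposed to doxycycline. Induction of Xist without doxycycline in part of the cells stays open, untested. The library was kept in the fits.

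Spen counts were higher in the SPOC line than in the GFP line, by 169 CPM (SE 7.89) untreated, 156 (SE 10.2) with Dox and 191 (SE 123) with Dox+Auxin, while the ratio was 1.97, 1.79 and 1.22. A rise of Spen in proportion is argued against, since the untreated ratio would give an excess of 836 CPM with Dox+Auxin and the observed one differed from that by -645 (SE 235). The excess with Dox+Auxin differed from the untreated one by 22.1 CPM (SE 123), too wide an error to show that they are the same, so reads of the SPOC construct counted with Spen stay a candidate explanation. Without GFP Dox+Auxin replicate 4 the excess was 292 CPM (SE 84.1), 123 more than untreated (SE 84.5) and -445 (SE 152) from the proportional one. Without replicate 1 or 2 of that group the difference from the proportional one was -696 (SE 314) or -643 (SE 322). The errors were widest there, so the case against a proportional rise was weaker. Another regulation of Spen in this line was not tested.

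The allelic columns were used in no comparison, and the lowest median BL/6J share of X-linked genes among them, 20.2%, is a signal outside the comparisons. As to the counts above the same-named totals, each of the 27 allelic pairs lay within exactly 1 total column of another name in all genes. Over genes with a mean of at least 200 allelic counts it also correlated best with that column. The lowest such r was 0.915, and the highest with a next best column was 0.861. Each pair held 34.1% to 35.0% of the counts of that column, against 23.6% to 51.3% of the same-named one. Every other total column was exceeded in at least 1303 genes, and no total column contained more than 1 pair. That the allelic columns stand in the order of their names is therefore argued against. No comparison of groups was made by the order that the totals give. That allelic reads were counted outside the totals is argued against, since the best column was exceeded in 0 genes. No biological explanation was tested. The BL/6J share of chromosome 16, also outside the comparisons, had a median of 33.4% over the 27 pairs, and the other 18 autosomes had medians of 49.4% to 51.6%.

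GFP Dox+Auxin replicate 2 also stood apart from its group, with X-linked output of -0.083 against -0.0572 to -0.0549. The lines differed in their change from untreated to Dox+Auxin in 441 genes. They also differed in the X-linked fall with Dox, which was smaller in the SPOC line by 0.23 (exact two-sided permutation p = 0.00794) and, without SPOC untreated replicate 2, by 0.17 (p = 0.0286, exact). These p were the same for all 2880 and 576 ways to match libraries within lines. Xist with Dox was also lower in the SPOC line, at 385 CPM against 840 CPM in the GFP line. Whether this accounts for the smaller X-linked fall was not tested.

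Other splits of the same libraries were counted for each comparison. In the 8 comparisons between groups only the real split gave as many genes, a share under 0.05. Splits that mix the groups also add the difference between groups to the spread, so low counts from them were partly fixed in advance. Such counts therefore cannot decide whether chance is the source of the real count. In the GFP line 1 of the 35 splits, the real one, gave as many genes for Dox against untreated (3837, highest other 1), for Dox+Auxin against untreated (7019, highest other 114) and for Dox+Auxin against Dox (8732, highest other 96). In the SPOC line 1 of 100 splits drawn did so for Dox against untreated (2478, highest other 1005), Dox+Auxin against untreated (6117, highest other 2231) and Dox+Auxin against Dox (5876, highest other 2456). Between the lines it was 1 of 100 untreated (2122, highest other 1314) and 1 of 100 with Dox+Auxin (4523, highest other 3293). In these highest others every library changed side except SPOC untreated replicate 3 or SPOC Dox+Auxin replicate 1. They were thus nearly the real split with its sides exchanged. For the interaction 3 of 100 splits drawn gave at least as many genes as the real 441, a share under 0.05, but the highest other gave 916. These splits exchange libraries between the lines within each treatment, which turns differences between the lines into an interaction, so a high count from one of them does not show a structure beyond the groups.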

How the results depend on the processing

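The alternatives for X-linked output and for the share of the Dox fall were chosen after the data had been seen, as was dropping SPOC untreated replicate 2 from the gene lists and from comparisons without its group, and matching libraries in other ways; the others were fixed before the data were examined. All counts of changed genes stayed within 1.5 times the main count under DESeq2 size factors, limma-voom, no filter, a mean of at least 5 CPM and autosomal genes only. The replicate block gave 4145 genes for SPOC Dox against untreated and 2006 for the interaction, where the DESeq2 Wald test gave 830 and a fit of only the groups compared 211; the cause was not tested. The numbers did not meet the rule set for pairing, as libraries of the same number correlated by over 0.1 in 10 of 12 pairs (GFP) and 14 of 15 (SPOC). Still, 11 of 12 and 12 of 15 libraries correlated best with their own number. The median r was 0.361 (GFP) and 0.446 (SPOC) for the same number, against -0.0954 and -0.121 for different numbers within the line. Failing the rule thus does not show that the libraries are unpaired, and these values point to pairing by number. The main fits hold no replicate term, so their spread includes differences between replicate numbers. Of the 2478 genes called for SPOC Dox against untreated, 2477 were also called with the block, as were all 441 of the interaction. The block moved no other count by over 1.5 times.

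With each library left out, counts ranged from 3026 to 3848 (Dox), 6325 to 7042 (Dox+Auxin) and 8034 to 8711 (Dox+Auxin against Dox) in the GFP line, and from 1953 to 2692, 5455 to 6063 and 5170 to 5926 in the SPOC line. SPOC against GFP gave 3399 to 4560 with Dox+Auxin and 1035 to 2171 untreated, with 1406 without SPOC untreated replicate 5, 1076 without GFP untreated replicate 1 and 1035 without GFP untreated replicate 2. The interaction gave 207 to 865: 253 without SPOC untreated replicate 4, 278 and 207 without GFP untreated replicates 3 and 4, and 232, 263, 236 and 865 without GFP Dox+Auxin replicates 1, 2, 3 and 4. The cause was not tested.

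With the estimated correlation 16 of 74 gene list calls held. This correlation was estimated over all 27 libraries with no replicate term. SPOC untreated replicate 2, whose X-linked genes lay apart as a set, was among them. Camera was not run without that library, so a lost call of an X-linked list does not show that the list was unchanged. X-linked output between the untreated lines turned from -0.01 to 0.0384 (exact p = 0.0286) without SPOC untreated replicate 2. The interaction reached -0.19 (exact p = 0.0286) without replicate 2 of SPOC untreated and Dox+Auxin; with all libraries its p was under 0.05 in 2208 of 2880 ways to match them. Ranges with each library left out were -0.63 to -0.61, -0.07 to -0.06 and 0.55 to 0.57 in the GFP line, -0.45 to -0.38, -0.25 to -0.18 and 0.19 to 0.20 in the SPOC line, and -0.0300 to 0.0384, -0.16 to -0.15 and -0.19 to -0.12 for untreated lines, Dox+Auxin lines and interaction. The share of the Dox fall in the GFP line was 15.1% over all genes tested and 11.8% as a mean over genes, with 8.98% to 10.6% for libraries left out, and 48.9% to 56.7% in the SPOC line. The 56.7% was without SPOC untreated replicate 2. Xist turned to -2.11 between untreated lines and 1.55 in the interaction without SPOC untreated replicate 2, whose Xist level shows the cause, over ranges of -2.11 to 2.85 and -3.41 to 1.55. Without that library Xist also gained its call in GFP Dox+Auxin against Dox (-0.75, adjusted p = 2.1e-04) and SPOC against GFP with Dox+Auxin (-0.56, adjusted p = 0.0044). Spen between the lines with Dox+Auxin gained its call with the block (adjusted p = 0.0435), in the Wald test (0.0468) and without GFP Dox+Auxin replicate 4 (3.4e-04). Spen in the interaction had adjusted p = 0.0547 without GFP untreated replicate 3.

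Of 215 gene values from the naming rule, 215 kept their direction and call with DESeq2 size factors, 204 with the Wald test (10 had no adjusted p and 1 gained its call) and 208 with the block (6 gained and 1 lost a call). Over all libraries left out, 2148 values kept both, 51 lost and 7 gained a call, and 2 turned. No simulation varied depth, so what it limits was not tested. The tests planned on allelic ratios and on the BL/6J share of chromosome X, with all their alternatives, were not run. The reason is that the totals contradict the column names. Fry with the block was not run because the numbers did not meet the rule set for pairing.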

Other observations

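No test in this part was chosen after its result was seen. Lists without mention in the report are given here for Dox+Auxin against untreated, in the GFP and then the SPOC line, by edgeR. Heat shock genes fell in 8 and 9 of 15 cases and rose in 3 and 2 (8 and 10, 3 and 2 adjusted over the list alone), with camera adjusted p = 0.093 and 0.018, and adjusted p = 0.63 and 0.46 with an estimated correlation. Of 18 MAPK feedback genes 8 and 11 fell and 3 and 4 rose (9 and 11, 4 and 4 adjusted over the list alone), with camera adjusted p = 0.11 and 0.074. Among them Dusp6, a phosphatase of ERK, was at -1.53 in the GFP line and -0.95 in the SPOC line. Of 16 Notch and RBPJ targets 7 and 7 rose and 5 and 4 fell (8 and 9, 5 and 4 adjusted over the list alone), and of 31 imprinted genes 12 and 11 rose and 7 and 5 fell (12 and 12, 7 and 5). Primitive endoderm genes rose in 5 and 4 of 13 cases (5 and 4 adjusted over the list alone), with 1 lower in the SPOC line. The camera adjusted p was 0.14 and 0.11 for Notch, 0.30 and 0.21 for imprinted and 0.062 and 0.23 for primitive endoderm genes.

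For the same comparisons, formative and primed genes rose in 4 and 3 of 13 cases and fell in 5 and 5 (4 and 4, 5 and 5 adjusted over the list alone), neural genes rose in 2 and 4 of 8 and fell in 2 and 3 (3 and 5, 2 and 3), and trophoblast genes rose in 3 and 2 of 9 and fell in 2 and 2 (3 and 2, 2 and 2). Germline genes rose in 5 and 2 of 18 and fell in 2 and 4 (5 and 2, 3 and 4), cell cycle genes rose in 3 and 2 of 20 and fell in 4 and 3 (3 and 2, 5 and 3), and interferon genes rose in 3 and 3 of 10 and fell in 3 and 2 (3 and 3, 3 and 2). Mitochondrial quality control genes rose in 3 and 1 of 10 and fell in 2 and 2 (3 and 1, 2 and 2), and fibroblast feeder genes rose in 2 and 1 of 8 and fell in 2 and 2 (3 and 1, 5 and 2). Of 7 genes of the NCoR SMRT HDAC3 complex 2 rose and 3 fell in the GFP line and 2 fell in the SPOC line (the same counts adjusted over the list alone). None of these 9 lists had a camera adjusted p under 0.05 here. Of 25 Xist silencing factors, 8 were higher in the SPOC than in the GFP line untreated (11 higher and 2 lower adjusted over the list alone), with camera adjusted p = 2.7e-04 and adjusted p = 0.13 with an estimated correlation.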
